A study of Mus musculus with 2 samples.

How the data were processed

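Primary hepatocytes of C57Bl6J mice were infected with an adenovirus carrying E2F1 and harvested 36 h later, per the labels' protocols. The cells were fixed in 1% formaldehyde for 10 min, and nuclear extracts were sonicated in 14 pulses of 30 s. Chromatin was pulled down with an anti-E2F1 antibody, and libraries of this DNA and of input chromatin were made for Illumina sequencing. The labels give 1 record of each kind. The series text describes 2 replicates, each made by combining 2 ChIPs. Only 1 peak list was analysed here, and whether the replicates were pooled before peaks were called is not given in the sources used here. The records of ChIP and input therefore enter as the groups of 1 comparison, made by the authors' peak caller, and no test between samples was run.

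The submitters' processing notes list the aligner Bowtie2 (2.1.0) and the mouse builds mm9 and NCBIM37, which name the same assembly. Column names show that peaks were called with MACS, per the file headers; its version and settings are not given in the sources used here. The deposited list gives for each peak the whole-number count of tags in the called region and the height of the pileup signal. The authors' fold is the ratio of ChIP tags to the background that the caller expects from the input. The deposited score is 10 times the negative log10 of the caller's p-value, and the authors' false discovery rate is a percent. A further column with values from 0.2222 to 0.6499 is explained nowhere in the sources used here. It was put through the permutation test described below, with medians of 0.534 in promoter peaks and 0.59 in other peaks (two-sided permutation p = 1e-05). Its meaning is unknown and no result below rests on it. All these values belong to single peaks and were used only to describe, rank or filter peaks within the list.

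The file held 6887 pairs of a peak and a gene for 5667 peaks, with 1 gene at 4450 peaks, 2 at 1214 and 3 at 3. Regions were 475 to 3999 bp long, the score started at 50, and the highest false discovery rate was 8.57%; 256 peaks had a rate of 0. Each peak was named for a gene around it or within 20000 bp. The caller's serial numbers ran from 2 to 18908 with 13241 of them not in the list, so the list is a selection whose rules are not given in the sources used here. Regions did not overlap each other. Read totals of the libraries are not given either, so no depth per library can be stated, and binomial intervals cover counting error over peaks or genes only.

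Each peak has a window of 301 bp centred on its summit, and the authors give the distance from this window to the TSS, with 0 where the window holds it. On entries for peaks downstream of a gene or in its 3' untranslated region, this distance was shorter than the gene in 81.4% of 656 and 100% of 35 entries checked. It was therefore taken there as the distance to the gene end and not used as a distance to the TSS. A promoter peak has its summit within 1000 bp of a TSS, that is, a window edge within 850 bp. Genes came from the authors' assignment, since no annotation of mm9 was used here. Coordinates are those of the file, counted from 1. Of 5587 gene symbols in the file, 5493 (98.3%) were matched by symbol or unique synonym to a RefSeq gene table of assembly GRCm38.p6, from which only names, coding status, gene order, gene lengths for the check above and gene numbers per chromosome were taken. The background for gene lists was the 21900 protein-coding genes of that table. A pseudogene or close paralog of a bound gene can receive reads of its relative, and aligner settings for reads with several matches are not given in the sources used here.

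The share of promoter peaks has an exact (Clopper-Pearson) 95% interval. Median strength of promoter and other peaks was compared by a two-sided permutation test with 100000 resamples. Peaks per chromosome were compared with gene number by a chi-square test. For 23 gene lists with 539 entries, Fisher's exact test (two-sided) compared members with all other background genes for having a promoter peak, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The count of each list was set beside those of 10000 random gene sets of the same size, and the median fold of its promoter genes beside that of 10000 random sets of promoter genes. Where a list had fewer than 3 promoter genes no median was given. Genes and peaks are not replicates, so each p describes this list of peaks.

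The lists cover the E2F family and pocket proteins, G1/S and replication licensing, DNA synthesis, DNA repair, G2/M and mitosis, apoptosis, lipogenesis, cholesterol, glycolysis, gluconeogenesis and glycogen, and insulin signalling. They also cover fatty acid oxidation, mitochondrial respiration, bile acids, secreted hepatocyte proteins, hepatocyte transcription factors, drug metabolism, urea cycle and amino acids, autophagy and circadian clock. Further lists hold ribosomal proteins, markers of other liver cell types, and genes not used in liver. The genes not used in liver are mostly neuronal and sensory, with some of muscle and the insulin gene Ins2. Lists, tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 peaks of highest fold, the 4 members of each list with the strongest promoter peaks, and 27 focus genes of the cell cycle and of glucose and lipid metabolism. Of these 27, 10 had a promoter peak, 7 a peak elsewhere only and 10 none listed. Some genes that the rule names are not reported here. Unions of lists and symbol families, and the search for clusters and near-identical peaks, were chosen after the data had been seen.

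The list test was checked on simulated data with 21900 genes in 200 runs. Lists with a planted share of 20% (18 members) were called in 5.5% of runs, of 40% (28 members) in 71%, and of 60% (30 members) and 80% (26 members) in 100%. Lists drawn at the background share were called in 0.737% of cases. A list of about 20 genes with a true share near 20% would therefore mostly be missed. No list was planted below the background share, so the power to call a deficit was not simulated. Alternatives varied the peak threshold, the promoter distance, the gene assignment, the background and the overlap of lists. Random placement of peaks, the E2F motif, CpG-rich promoters and chromosome length need the genome of the build and were not analysed here. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.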

Results

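The data described here are a list of genomic regions called as enriched over input with an anti-E2F1 antibody. They come from primary mouse hepatocytes, the main cell type of the liver. E2F1 is a transcription factor known for activating genes of S phase entry. The cells, of strain C57Bl6J, carried an adenovirus that delivers E2F1 and were fixed 36 h after infection. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA that an antibody pulls down with its protein. The labels give 1 ChIP record and 1 input record, the input being chromatin taken before the pull-down. The series text speaks of 2 replicates, but the peak list is not split by replicate, so none of the values below carries a replicate error. No cells without the E2F1 vector were analysed here. Numbers of reads per library are not given in the sources used here, so the depth is unknown, and the tag counts of single peaks do not give it.

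The list held 5667 peaks, named for 5594 genes. The median peak had a fold enrichment over input of 4.93 (quartiles 3.77 and 7.28, range 2.28 to 70.6). It held 149 tags (quartiles 99 and 221) in a region of 1914 bp, with a false discovery rate of 1.84%. Fold, tags and false discovery rate are the authors' values for each peak. The strongest peak lay at H2afx, which codes for the histone variant phosphorylated at DNA breaks, on chromosome 9 from 44142372 to 44142672 (mm9). Its fold was 70.6 and it held 885 tags. The second, with a fold of 57.58 and 417 tags, lay 7099 bp upstream of Maneal on chromosome 4 from 124546515 to 124546815. A peak at the shared promoter of Cchcr1 and Tcf19 had a fold of 49.01 on chromosome 17 from 35653637 to 35653937. The promoter of Cdk1, the kinase that drives entry into mitosis, had a fold of 45.17 on chromosome 10 from 68815641 to 68815941. Mcm3, a subunit of the replicative helicase, had a fold of 38.65 on chromosome 1 from 20810274 to 20810574.

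The next 5 peaks by fold also lay at promoters. They were at Psmc4, an ATPase subunit of the proteasome (fold 38.25), and at Nop58, a core protein of small nucleolar ribonucleoproteins (fold 38.21, 1027 tags). Hist2h4, a histone H4 gene, followed with a fold of 37.78 and Ppil1, a peptidyl-prolyl isomerase of the spliceosome, with 36.81. The promoter shared by Cnpy4 and Taf6, a subunit of the general transcription factor TFIID, had a fold of 36.75. Of the 10 strongest peaks, the peak upstream of Maneal was the only one outside a promoter, taken as a summit within 1000 bp of a transcription start site (TSS).

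The first comparison asked where the listed E2F1 peaks lay relative to genes. Each listed peak lies in a gene or within 20000 bp of one, and 13241 of the caller's serial numbers are not listed. The shares below are therefore shares of this list and not of all E2F1 binding. Random placement of peaks was not run, so they have no expected value beside them. Promoters held 2612 of the 5667 peaks, or 46.1% (exact binomial 95% interval 44.8% to 47.4%). These peaks named 2934 genes, of which 45 could not be matched to the reference table and so have no known coding status. The matched ones covered 2866 protein-coding genes, equal to 13.1% of the 21900 protein-coding genes in the reference table. A pair of promoters shared the same peak in 331 cases. The 301 bp window around the summit held a TSS in 1400 peaks (24.7%). Another 901 windows ended 1 to 350 bp from a TSS, 639 of them upstream and 262 downstream. At the other end, 1387 peaks (24.5%) lay inside genes more than 20000 bp from the TSS. By the authors' own classes, 2625 peaks were at promoters and 2285 (40.3%) inside genes. A further 382 lay upstream, 339 downstream and 36 in 3' untranslated regions.

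Promoter peaks were stronger than the others. Their median fold was 6.48 against 4.07 for the remaining 3055 peaks, a ratio of 1.59 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Median tag counts were 169 and 136, and median false discovery rates 0.65% and 3.62%. The median fold went from 6.9 where the window held the TSS to 3.81 at more than 20000 bp. Of the 723 peaks with a fold of at least 10, 79.3% lay at promoters, and of the 27 with a fold of at least 30, 92.6% did. In the 1417 peaks of lowest fold the promoter share was 13.5%. Peaks are not replicates, so this p describes the list and not the variation between cultures.

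**Figure D1:**
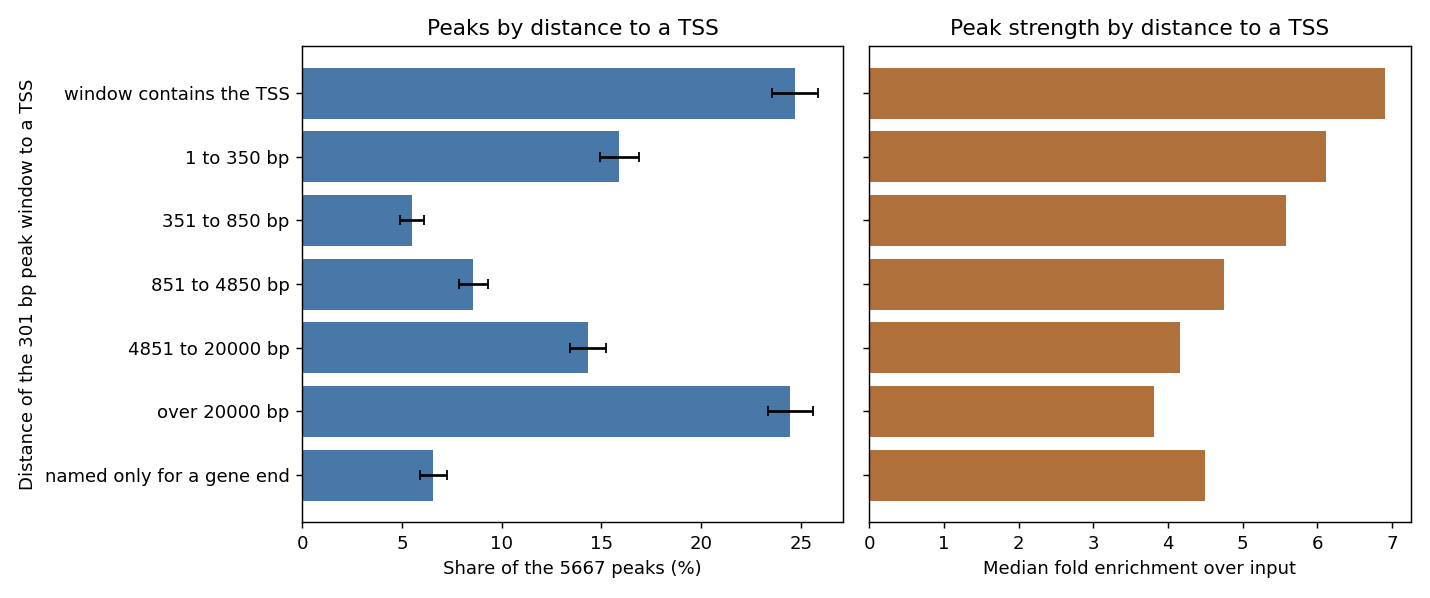
Left, share of the 5667 peaks (x axis, percent, with exact binomial 95% intervals) by the distance between the 301 bp peak window and the TSS (y axis, bp); right, the median fold enrichment over input (x axis) of the same classes. Windows that held a TSS made up 24.7% of peaks with a median fold of 6.9, and those over 20000 bp away 24.5% with a median of 3.81.

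Across chromosomes, X and Y held fewer peaks than their number of protein-coding genes would give. The gene numbers are those of assembly GRCm38.p6, while the peaks are on mm9. How many of these genes mm9 holds, or reads can be placed at, was not checked, so the deficits may not be properties of E2F1 binding. Chromosome X had 126 peaks against 250.1 from its gene number, a ratio of 0.504 (95% interval 0.42 to 0.599), and chromosome Y had 4 against 66.3. Among the autosomes, chromosome 7 was lowest with a ratio of 0.761, and chromosome 14 followed with 0.808. Chromosome 18 was highest with a ratio of 1.33, ahead of chromosome 8 with 1.21. The distribution differed from that of the genes (chi-square 223.3 with 20 degrees of freedom, p = 2.59e-36). Without olfactory, vomeronasal and predicted genes in the gene numbers, the distribution still differed (chi-square p = 1.29e-13). The ratio on chromosome X was then 0.507, and ratios of single autosomes under that setting are not given here. With promoter peaks alone the ratio on chromosome X was 0.668. The labels do not give the sex of the mice.

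The next comparison asked which genes had a listed E2F1 peak at their promoter, by 23 gene lists fixed before the data were examined. Genes of the cell cycle had promoter peaks more often than other genes. Of the genes for DNA synthesis and nucleotide supply, 24 of 30 (80.0%) had a promoter peak, against 13.1% of all protein-coding genes. The list of G1/S control and replication licensing had 20 of 28 (71.4%), that of DNA repair and checkpoints 18 of 26 (69.2%), and that of G2/M and mitosis 16 of 28 (57.1%). By Fisher's exact test, two-sided and Benjamini-Hochberg adjusted over the 23 lists, the odds ratios were 26.8 (adjusted p = 3.60e-15), 16.7 (2.55e-11), 15.0 (5.06e-10) and 8.90 (2.61e-07) in that order. For none of these lists did any of 10000 random gene sets of the same size hold as many promoter genes. Among only the 5406 protein-coding genes named for any peak, a comparison that asks whether a peak lies at the promoter and not elsewhere, the mitosis list did not pass (odds ratio 2.85, adjusted exact p = 0.213).

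The peaks at these promoters were also strong. Their median fold was 14.41 for DNA synthesis, 13.7 for repair, 12.36 for G1/S and 11.855 for mitosis, against 6.525 over all 2866 promoter genes. These medians lay at the percentiles 100, 100, 100 and 99.95 of random sets of promoter genes of the same sizes. In the DNA synthesis list, Top2a, a topoisomerase that untangles sister chromatids, had a fold of 34.97 on chromosome 11 from 98885491 to 98885791. Fen1, the flap endonuclease of lagging strand synthesis, had 30.31, Rpa2, which coats single-stranded DNA, 28.82, and the primase subunit Prim1 23.11. The Fen1 peak also lay at the promoter of 1810006K21Rik. Behind Mcm3 in the G1/S list came Cdc25a, a phosphatase that activates cyclin-dependent kinases, with a fold of 31.66, Gins2 with 24.79 and Mcm6 with 19.06. Ccne1, the gene of cyclin E1, had a fold of 17.26 on chromosome 7 from 38892842 to 38893142 and a peak past its 3' end with 19.43. Cdc6, which loads the helicase at origins, had a fold of 16.63 and Mcm2 9.13.

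In the repair list, H2afx was followed by Blm, the helicase lost in Bloom syndrome, with a fold of 21.09, by Xrcc2 with 19.06 and by the cohesin subunit Smc1a with 17.25. The Smc1a promoter is shared with Ribc1. In the mitosis list, Plk1, a mitotic kinase, had a fold of 30.82 and Kif20a, a kinesin of cytokinesis, 28.89 at a promoter shared with Brd8. Top2a stood in both the synthesis and the mitosis list. Members without a promoter peak included Pcna, Rrm2, Mcm4, Mcm7, Brca1, Ccnb1 and Foxm1, chosen here after their values were seen.

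**Figure D2:**
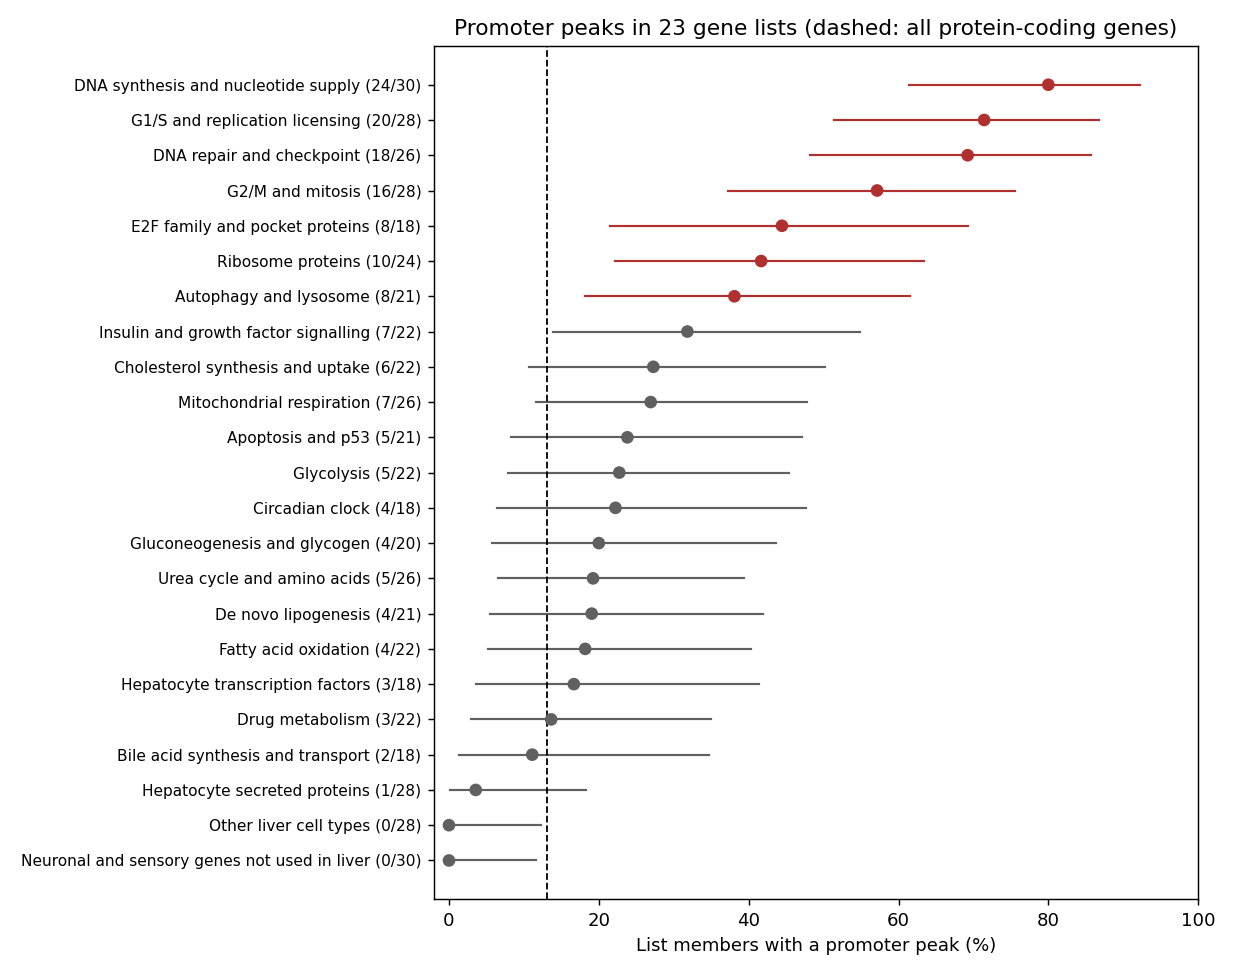
Share of the members of each of 23 gene lists that had a promoter peak (x axis, percent; points with exact binomial 95% intervals; counts in brackets), with red marking lists that passed the adjusted Fisher's exact test and the dashed line the 13.1% of all protein-coding genes. The 4 cell cycle lists lie between 57.1% and 80.0%. The 2 lists of other liver cell types and of neuronal, muscle and other genes not used in liver lie at 0.

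Some E2F family members and their partners in the retinoblastoma pathway carried promoter peaks themselves. Of 18 such genes, 8 had one (44.4%, odds ratio 5.33, adjusted exact p = 0.00421), and 14 of 10000 random sets held as many. E2f3, an activator of the same class as E2F1, had a fold of 27.33 on chromosome 13 from 30077795 to 30078095. Mybl2, a partner of the MuvB complex, had a fold of 18.85, Rbl1, the gene of p107, 11.72, and the repressor E2f7 7.72. The retinoblastoma gene Rb1 had a weaker peak, with a fold of 4.54. The 10 members without a promoter peak were E2f1, E2f2, E2f4, E2f5, E2f6, E2f8, Tfdp1, Rbl2, Lin9 and Lin52. The median fold of the 8 genes, 6.645, lay at percentile 50.6 of random sets. With the 1416 peaks of highest fold, or with peaks in gene bodies counted, the family no longer passed (adjusted exact p = 0.0568 and 0.0519), nor among only the genes named for any peak (0.379).

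At E2f1 itself the list held 0 peaks, at its promoter or over its exons. The question had been whether vector sequence would appear there as a peak over exons. E2f8 also had none. E2f2 had a peak 4889 bp upstream of its TSS with a fold of 3.44, on chromosome 4 from 135723119 to 135723419. The list shows regions of at most 3999 bp and leaves out 13241 of the caller's serial numbers, so the absence of a listed peak does not show whether E2F1 was bound.

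Genes of lipid synthesis held peaks at a few of their promoters. Of 21 genes of de novo lipogenesis 4 had a promoter peak (19.0%, odds ratio 1.56, adjusted exact p = 0.440), a share that did not pass the test. The odds ratio was below 1 with promoters of 500 bp (0.814), with the authors' promoter class (0.694) and with the 1416 peaks of highest fold (0.862). It was 2.92 with gene bodies counted (9 of 21, adjusted exact p = 0.0519), and the list passed with all annotated genes as the background (3.84, adjusted exact p = 0.0434). Fasn, the fatty acid synthase, had a fold of 9.34 with 109 tags on chromosome 11 from 120685733 to 120686033, with the window edge 240 bp upstream of the TSS. Mlxipl, the gene of the glucose-responsive factor ChREBP, had a fold of 7.06 with 300 tags on chromosome 5 from 135583576 to 135583876, inside the gene with the window edge 804 bp downstream of the TSS. The desaturase gene Fads1 had a fold of 6.11 and Lpin1, a phosphatidate phosphatase, 5.29. Acaca, Elovl6 and Srebf1 had peaks inside the gene and away from the promoter. Their folds were 3.85 for Acaca at 50691 bp, 3.12 and 5.82 for Elovl6, and 2.84 for Srebf1 at 10004 bp. Acly and Scd1 had no listed peak.

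Of 22 genes of cholesterol synthesis and uptake, 6 had a promoter peak (27.3%, odds ratio 2.49, adjusted exact p = 0.122). With all annotated genes as the background this list passed (odds ratio 6.13, adjusted exact p = 0.00284). Insig1, which retains the sterol sensor in the endoplasmic reticulum, had a fold of 11.17, the farnesyl diphosphate synthase Fdps 8.97, the squalene synthase Fdft1 8.41 and the mevalonate kinase Mvk, at a promoter shared with Mmab, 7.74.

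For glycolysis the count was 5 of 22 (22.7%, odds ratio 1.95, adjusted exact p = 0.302). The folds were 9.29 at Pgk1, 8.77 at Pfkm, whose promoter peak also serves Senp1, 8.06 at Pfkfb1 and 5.48 at Tpi1. With promoters widened to 5000 bp the glycolysis list passed, at 8 of 22 (odds ratio 3.17, adjusted exact p = 0.0327). Pklr, the liver pyruvate kinase, had no listed peak. For gluconeogenesis and glycogen the count was 4 of 20 (odds ratio 1.66, adjusted exact p = 0.435). Pyruvate carboxylase, Pcx, had a fold of 8.95, the transcription factor Foxo1 7.84, Pck2 5.99 and Ppp1r3b 4.25. Pck1 and Ppargc1a had no listed peak. G6pc, which codes for glucose-6-phosphatase, had a peak 5234 bp upstream with a fold of 4.47, and Fbp1 a peak past its 3' end with a fold of 3.97.

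In fatty acid oxidation 4 of 22 genes had a promoter peak (18.2%, odds ratio 1.48, adjusted exact p = 0.598). The strongest was at Pdk4, the kinase that shuts off pyruvate dehydrogenase, with a fold of 14.64 and 283 tags on chromosome 6 from 5446573 to 5446873. Acaa1a, whose promoter is shared with Myd88, had a fold of 7.37. Insulin and growth factor signalling had 7 of 22 (31.8%, odds ratio 3.10, adjusted exact p = 0.0535). Among these were Rictor with a fold of 9.57, the insulin receptor gene Insr with 6.97, Tsc2 with 6.83 and Irs2 with 5.86. This list passed when only the gene closest to each peak was counted (odds ratio 3.54, adjusted exact p = 0.0292). It also passed with promoters widened to 5000 bp, with the authors' promoter class, with gene bodies counted and with all annotated genes as the background. The odds ratio was lower with the 2833 peaks of lowest p (2.16), with promoters of 500 bp (1.72) and among genes named for any peak (1.03), and below 1 with the 1416 peaks of highest fold (0.821, 1 of 22 genes).

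Ribosomal protein genes and autophagy genes completed the 7 lists that passed. Of 24 ribosomal protein genes 10 had a promoter peak (41.7%, odds ratio 4.76, adjusted exact p = 0.00227), with folds of 19.02 at Rpl3, 13.96 at Rps19 and 13.66 at Rpl7. Families taken by symbol prefix after the data had been seen, which also hold a few genes of other function such as Rps6ka5, did not pass: 14 of 53 genes named Rpl (26.4%, odds ratio 2.39) and 8 of 44 named Rps (18.2%, odds ratio 1.48) had a promoter peak (adjusted exact p = 0.0750 and 0.598 over 285 families). Of 21 autophagy and lysosome genes 8 had one (38.1%, odds ratio 4.10, adjusted exact p = 0.0117). The median fold of their peaks was 5.55, at percentile 18.1 of random sets. The highest was 7.63 at Tcfeb, the gene of the lysosomal regulator TFEB. Neither list passed among only the genes named for any peak (adjusted exact p = 0.546 and 0.379). Autophagy also lost its call among the 2833 peaks of lowest p (adjusted exact p = 0.550) and with gene bodies counted (0.0519), and its odds ratio was 0.862 among the 1416 peaks of highest fold.

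Apoptosis genes had promoter peaks at 5 of 21 (23.8%, odds ratio 2.08, adjusted exact p = 0.300). The median fold of these peaks lay at percentile 96.0 of random sets. Casp8, which codes for the protease that starts death receptor signalling, had a fold of 13.8 and Cdkn2a, the gene of p16 and p19Arf, 8.98. Mitochondrial respiration had 7 of 26 (26.9%, odds ratio 2.45, adjusted exact p = 0.136), with the highest fold, 10.12, at Ndufv1 of complex I. The circadian clock had 4 of 18 (22.2%, odds ratio 1.90, adjusted exact p = 0.405), with 7.12 at Dbp. The clock list passed with all annotated genes as the background (odds ratio 4.67, adjusted exact p = 0.0291), and its odds ratio was below 1 with the 2833 peaks of lowest p (0.571), the 1416 of highest fold (0) and promoters of 500 bp (0.966). With all annotated genes as the background, the lists of apoptosis, glycolysis, gluconeogenesis, fatty acid oxidation and respiration also passed (odds ratios 5.10, 4.80, 4.08, 3.63 and 6.02, adjusted exact p = 0.0125, 0.0142, 0.0392, 0.0477 and 0.00135). Protein-coding genes as a whole already stand above that background, so these passes show no excess over other protein-coding genes.

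In 4 lists of differentiated hepatocyte function, the share of genes with a promoter peak did not differ detectably from that of other protein-coding genes. The main test could not call a lower share in lists of this size. Even 0 of 28 genes, the count for markers of other liver cell types, did not pass (adjusted exact p = 0.0993). The counts were 2 of 18 for bile acid synthesis and transport (odds ratio 0.830, adjusted exact p = 1), 3 of 22 for drug metabolism (1.05, p = 1) and 5 of 26 for the urea cycle and amino acids (1.58, p = 0.455). The amino acid list passed with all annotated genes as the background (3.89, adjusted exact p = 0.0269) and had an odds ratio of 0.690 with the 1416 peaks of highest fold. Secreted hepatocyte proteins had 1 of 28 (odds ratio 0.246, adjusted exact p = 0.295), at Ahsg, the gene of fetuin-A, with a fold of 8.91. Alb, the albumin gene, had no listed peak. The folds were 10.13 at Nr1h2 and 4.98 at Nr0b2 for bile acids, 8.66 at Cyp2b10 for drug metabolism, and 8.89 at Shmt2 and 7.17 at Glul for amino acids. Hepatocyte transcription factors had 3 of 18 (odds ratio 1.33, adjusted exact p = 0.791), with folds of 7.29 at Cebpa, 7.28 at Foxa3, whose peak also lies at the Sympk promoter, and 3.71 at Foxa2. Hnf4a had 3 peaks inside the gene, the strongest with a fold of 10.08 on chromosome 2 from 163364918 to 163365218.

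Markers of Kupffer, stellate, endothelial and biliary cells had 0 promoter peaks in 28 genes (adjusted exact p = 0.0993), and none was named at any distance. The list of neuronal, sensory and other genes not used in liver had 0 in 30 (adjusted exact p = 0.0687), with 5 named for peaks elsewhere. That list also holds the heart and muscle genes Myh6, Actn2, Ckm and Ttn and the insulin gene Ins2. Neither list passed, although the upper exact 95% limits of their shares, 12.3% and 11.6%, lay below the 13.1% of all genes. The list of other cell types passed as lower with promoters of 5000 bp (adjusted exact p = 0.0367) and with gene bodies counted (0.0132), and both lists did without olfactory, vomeronasal and predicted genes in the background (0.0444).

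Lists were then set against each other, in 6 comparisons chosen after the data had been seen. The 4 cell cycle lists together had promoter peaks at 77 of 111 genes (69.4%). Ribosome and respiration genes, active in most cells, had them at 17 of 50 (34%), so the cell cycle genes exceeded these with an odds ratio of 4.40 (two-sided exact p = 3.21e-05, adjusted p = 9.62e-05). The median fold was 13.07 against 6.17 (two-sided permutation p = 0.00178, adjusted p = 0.0107). The 5 lists of carbohydrate and lipid metabolism together had 23 of 107 (21.5%), below the cell cycle genes (odds ratio 8.27, adjusted exact p = 4.35e-12) and with a lower median fold of 7.37 (adjusted permutation p = 0.0221). These metabolic genes stood above all other genes, at 13.0%, by an odds ratio of 1.83 (exact p = 0.0140, adjusted p = 0.0210). That call ended with promoters of 500 bp, with the authors' promoter class and without olfactory, vomeronasal and predicted genes in the background. Among genes named for any peak the odds ratio was 0.970. The 4 lists of bile acid, secreted protein, drug and amino acid genes, with 11 of 94 (11.7%), did not differ detectably from all other genes (odds ratio 0.880, adjusted exact p = 0.878) or from the metabolic genes (odds ratio of these over them 2.07, adjusted exact p = 0.107). The chosen ribosome and respiration genes stood above all other genes (odds ratio 3.44, adjusted exact p = 0.000249), while respiration alone and the Rpl and Rps families did not pass.

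**Figure D3:**
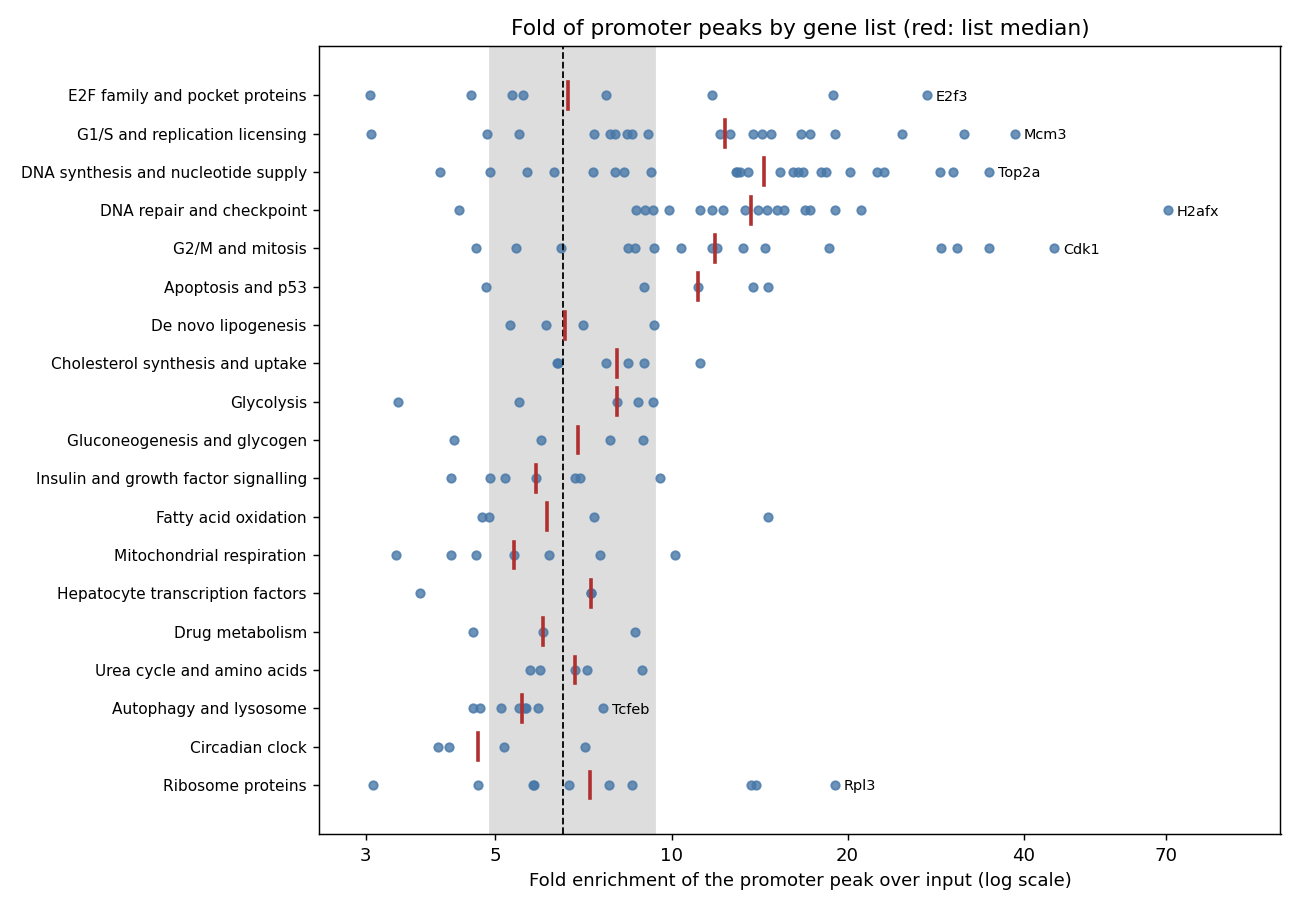
Fold enrichment over input of each promoter peak (x axis, log scale) by gene list (y axis); each point is a gene, red bars are list medians, the dashed line and the grey band are the median and quartiles of all promoter genes (6.525, 4.89 and 9.3575), and the strongest gene is named for each list that passed the test. Medians of the 4 cell cycle lists lie between 11.855 and 14.41, and those of the 5 carbohydrate and lipid lists lie within the band.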

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

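Unions of lists, and the settings with only genes named for any peak as the background, without olfactory, vomeronasal and predicted genes, with the closest gene only, with pileup height, with shorter regions and with promoter peaks per chromosome, were chosen after the data had been seen. Over 12 alternatives, 223 of 274 list results kept their direction and their side of the threshold, 8 lost the call, 19 gained one and 24 changed direction, 23 of these with no call before or after; 2 further list results had no finite odds ratio. G1/S, DNA synthesis and DNA repair passed under each of the 12, and the 4 cell cycle lists together had odds ratios from 6.35 to 37.9 under the 11 run for them. Keeping the peaks of lowest p left 2833, with 65.4% at promoters, and keeping those of highest fold left 1416, with 76.1%; promoters of 500 and 5000 bp gave 40.6% and 54.6%. With all annotated genes as the background, where a promoter gene is rarer (5.78% of genes), the number of lists passed, 7, became 17. Protein-coding genes as a whole, at 13.1%, already stand above that share, so lists of such genes pass more easily there. Among genes named for any peak the number became 3. That last setting conditions on a peak and so asks where it lies, not whether members have one at the promoter more often than all genes. It gave odds ratios of 3.55 for the E2F family and likewise 3.55 for autophagy, 2.85 for mitosis, 2.22 for ribosomal proteins and a reversed 0.970 for the metabolic union. The E2F family lost its call at 4.94 with the peaks of highest fold and at 3.11 with gene bodies counted. Autophagy gave 1.62 with the peaks of lowest p, a reversed 0.862 with those of highest fold (1 of 21 genes) and 2.92 with gene bodies. The metabolic union lost its call at 1.46 with 500 bp, 1.52 with the authors' promoter class and 1.55 without olfactory, vomeronasal and predicted genes. Of the lists without a call, odds ratios changed direction among genes named for any peak for apoptosis and glycolysis (0.886 each), fatty acid oxidation (0.886), lipogenesis and gluconeogenesis (0.709 each) and hepatocyte transcription factors (0.443). With the peaks of highest fold they did for lipogenesis (0.862), insulin signalling (0.821), drug metabolism (0.821), amino acids (0.690), the circadian clock (0, with 0 of 18 genes) and bile acids (1.01). With 500 bp they did for lipogenesis (0.814), hepatocyte transcription factors (0.966) and the circadian clock (0.966). The others were lipogenesis with the authors' class (0.694), the clock with the peaks of lowest p (0.571), hepatocyte transcription factors with the closest gene only (0.947), and bile acids with gene bodies (1.94) and all annotated genes (2.04). Drug metabolism moved to 0.874 with 5000 bp, 0.613 with gene bodies and 0.888 without olfactory, vomeronasal and predicted genes. For these losses and changes the cause was not tested. The ratio of promoter to other peaks stayed above 1 for score, tags and height (1.98, 1.24 and 1.62), and that of chromosome X below 1 (0.507 and 0.668). Merging overlapping peaks left 5667. Random placement, all motif alternatives, the CpG-rich background and chromosome length were not run, since they need the genome of the build. No paired analysis was possible because each group has 1 record. The depth of the libraries is unknown, so what a deeper library would add to the list cannot be stated.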

Other observations

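The test of the length limit, the comparison with ribosome and respiration genes and both tests on the strong clusters were chosen after their results were seen, as were the symbol families, histone genes, near-identical peaks and clusters themselves. Beyond the fixed lists, genes were grouped by symbol prefix into 285 families of at least 10 protein-coding members, and 21 families differed from the background of 13.1% (two-sided Fisher's exact test, adjusted over the families), 14 above it and 7 below. Centrosomal Cep genes had promoter peaks at 19 of 38 (50%, adjusted exact p = 2.61e-06), led by Cep57, Cep152 and Cep128. Nucleoporins, which build the nuclear pore, had them at 12 of 21 (57.1%, adjusted exact p = 9.37e-05), among them Nup85 and Nup214, and Rad genes at 12 of 20. Intraflagellar transport genes, which serve the primary cilium, had 8 of 14 (57.1%, adjusted exact p = 0.00349), led by Ift140 and Ift80. Mitochondrial ribosomal Mrpl genes had 16 of 49 (adjusted exact p = 0.00860), the kinesins named Kif 12 of 38 with a median fold of 10.285 (adjusted exact p = 0.0354), and the deadenylase subunits named Cnot 6 of 11 (adjusted exact p = 0.0228). On the low side, olfactory receptors had 1 of 1110, interleukins and their receptors named Il 2 of 83 (adjusted exact p = 0.0263) and collagens named Col 0 of 44 (adjusted exact p = 0.0421). Predicted genes named Gm (3 of 1329) or LOC (0 of 138) and vomeronasal Vmn genes (0 of 355) were also low. How many of these or the olfactory genes mm9 holds, or reads can be placed at, was not checked. A low call also needs a large family, since 0 of 42 Defb genes missed the threshold (adjusted exact p = 0.0546). The cytochrome P450 family, with 4 of 99, missed the threshold (adjusted exact p = 0.0529).

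Histone genes had promoter peaks at 13 of 68 (19.1%), against 13.1% of all genes, a difference that was not detectable (odds ratio 1.57, two-sided exact p = 0.148). Over these genes the fold ran from 4.9 at Hist2h2bb to 70.6 at H2afx with a median of 13.41, and 3 of the 10 peaks counted for 2 histone genes each; whether they differ in strength from other promoter peaks was not tested. Hist1h4i (5.11) and Hist4h4 (6.25) were among the weaker ones. On chromosome 13 the shared promoter of Hist1h2ah and Hist1h2bk had a fold of 35.43 and that of Hist1h2bj and Hist1h2ag 32.11. The cell cycle inhibitor gene Cdkn2d (chromosome 9, 21095861 to 21096161) and the predicted gene Gm4694 (chromosome 9, 123836350 to 123836650) had nearly the same peak, with folds of 35.39 and 35.26, tags of 400 and 399, and regions of 1601 bp each. Reads shared between copies were not examined for this pair. The gene model AC114005.5 was named for 15 peaks up to 4289638 bp from its start, and was the closest gene for 2 of them.

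E2f1 and 30 other genes of the E2F family and cell cycle lists had no listed peak, although many other members of these lists did. A candidate explanation is that calls were made there and then left out of the list. Regions end sharply at 3999 bp, with 193 regions (3.41%) from 3750 to 3999 bp, 214 in the class below and 0 longer, which fits a length limit that would remove wide calls. Of the 31 genes, 96.8% had at least 1 skipped serial number of the caller between the listed peaks on either side, with 2 between Mapre1 and Raly around E2f1, 1 around Pcna and 0 around Foxm1. That share lay at percentile 99.92 of sets of other unlisted genes (median 77.4%, 95% of sets from 61.3% to 90.3%). The sets were matched on the number of genes between flanking peaks, with large numbers pooled in a single class. They were not matched on gene family or activity, so the percentile cannot show that cell cycle genes in particular lost calls. A skipped number does not place a call at a given gene. Whether width, another filter or an unbound promoter accounts for each gap stays open.

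The excess of promoter peaks at cell cycle genes was weighed against 2 technical readings. If peaks formed alike at any active promoter, ribosome and respiration genes should match the cell cycle genes. The odds ratio between them was 4.40 (two-sided exact p = 3.21e-05). Promoter activity was not measured, and other symbol families differed widely, with 57.1% for Nup, 54.5% for Cnot and 18.2% for Rps. The chosen genes may thus not stand for all active promoters, and the comparison shows only an excess over those genes. If neighbours were counted through shared promoters, counting only the closest gene should remove the excess, but 64% of the 111 genes still had a promoter peak against 11.7% of all genes (odds ratio 13.8, exact p = 5.03e-39). What accounts for the excess stays open, since the E2F motif and the CpG content of promoters were not analysed here. Binding by the endogenous protein and by the overexpressed one cannot be separated here, since no cells without the vector were analysed.

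A pair of groups of strong peaks lay outside promoters, 6 peaks around Tex14 and Rad51c (chromosome 11, 87235938 to 87285219, folds 12.37 to 16.46) and 6 around Snx6 and Gm16382 (chromosome 12, 55811371 to 55839531, folds 11.47 to 14.25). Another group on chromosome 7 (19876010 to 19945399, around Rtn2, Fosb and Ercc1, 4 peaks, implied background 8.48) was set aside after a first look because 2 of its peaks lie at promoters. Extra copies or repeats in these cells may raise ChIP and input together. A rise of both alike would leave their ratio unchanged, so by itself it would not account for the folds of these peaks. The background implied by pileup height over fold was higher by 8.34 in the 12 peaks than in 707 other peaks of fold 10 or more (medians 17.7 and 9.36). With each of the 2 groups counted once, by its median, the two-sided exact permutation p for a difference of means was 0.00785. The 2 groups were chosen to hold no promoter peak, whereas 573 of all 723 peaks of fold 10 or more lay at promoters. Clustering and position outside promoters were therefore not separated. Against 156 peaks in the same range of height the difference was 6.03 (exact permutation p = 0.0668, counted likewise), so extra copies and the height of the peaks themselves cannot be told apart with 2 groups, and no biological explanation was tested.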
